A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

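RNA sequencing measured gene expression in the intestine of rainbow trout (Oncorhynchus mykiss) 48 h after an intraperitoneal injection. Per the labels, 3 samples came from fish injected with infectious hematopoietic necrosis virus (IHNV, a rhabdovirus of salmonid fish) and 3 from fish injected with M199. M199 is the name of a cell culture medium, and the labels name it as the control treatment. Per the labels' protocols, total RNA was extracted with TRIzol and libraries followed standard Illumina procedures. The labels do not say whether the 3 samples of a group are separate fish or pools, so the p-values measure the spread between these samples, which may be partly technical.

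The authors deposited 1 table of 42350 rows. Per the file headers, it holds a raw count and an FPKM value for each gene in each of the 6 samples, the authors' mean FPKM of each group, a log2 fold change, a p-value and an adjusted p-value. The submitters' processing notes name fastp, Bowtie2 2.2.8 and DESeq2, without saying at which step each was used. The genome build, the annotation release, the counting tool and whether counting used strand are not given in the sources used here. The deposited counts were whole numbers with different totals per sample. The deposited FPKM values had 2 decimals. Over the 1013 genes above 50 FPKM in all 6 samples, each value equalled the count divided by the sample total and by 1 length per gene, with a median coefficient of variation of 0.0045% between samples. In the deposited group means a value of 0 had been replaced by 0.001. The authors' deposited log2 fold changes equalled the log2 ratio of those means to within 2.2e-07, so they carry no further scaling. The test behind the deposited p-values is not named in the table. Every count and FPKM column was tied to a sample by its name.

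Of the rows, 39849 carried an NCBI gene ID, and all of these were found in the reference gene table used for names (assembly USDA_OmykA_1.1). Another 2488 rows were loci assembled from the reads with MSTRG numbers, which took 5.5% of the counts, and 13 were mitochondrial genes. No row lacked an identifier. Names and descriptions are those in the deposited table. They come from best sequence matches, and 17827 descriptions name a hit in another species, so that a symbol and its description can disagree and several rows can share a symbol. Salmonids hold many duplicated gene copies. Reads from near-identical copies could have been split or assigned to either copy, and values of single copies of the chemokine, heat shock, globin, mucin and interferon-induced families are uncertain for that reason. The same holds for overlapping and antisense genes, because the use of strand is not given.

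Total counts per sample were 19921144, 13530619 and 31142883 in M199 replicates 1 to 3 and 15677263, 15108957 and 15610499 in IHNV replicates 1 to 3. The 10 most abundant genes took between 7.23% and 8.44% of the counts of a sample, and mitochondrial genes took between 3.18% and 3.54%. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 10.9 and 26.7, so no sample was a copy of another.

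The test written before the data were examined was limma on log2(FPKM + 1), with edgeR named in its place should the table hold counts. It does, and edgeR's quasi-likelihood test on the counts (edgeR 4.0.16 in R 4.3.3) is therefore the main test. Genes with an FPKM of at least 1 in at least 3 of the 6 samples were kept, whatever their group, which left 22964. Library sizes were scaled with TMM, and the scaling factors lay between 0.94 and 1.08. The model held the group alone. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are library-size-scaled counts (edgeR's cpm, written CPM) over the TMM-scaled library sizes, as mean ± SD over the 3 samples of a group. Where all 3 libraries of a group held no count, a lower bound of the fold was computed against 3 counts over that group. Such floors cover counting error only.

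Lists of genes for 31 pathways and cell types were fixed before the data were examined, with symbols and description words. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists, and beside it with camera with an estimated correlation and with fry. Some lists took in other genes through their description words, and these are named with the result. Smaller groups within lists were chosen after their values were seen. KEGG pathways and GO processes of the deposited annotation with 10 to 300 tested genes were tested with a one-sided Fisher's exact test, separately for genes higher and lower, against the tested genes that carry a term of that annotation. The genes named in the text follow a rule set before the data were examined. The first part took the 12 largest rises and the 12 largest falls past the threshold whose 3 values in 1 group all lay on the same side of the 3 in the other, with a mean FPKM of at least 2 in the higher group and an informative name. The second part took up to 4 members with the smallest p-value of each list. The last part took a fixed set of sentinel genes of infection and of cell types. Exceptions are said to be such. Some genes that the rule selects are not reported here.

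The alternatives were limma 3.58.1 on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 5, without trend, with robust moderation or with array weights, FPKM rescaled to the same sum in each sample or quantile-normalized, median-of-ratios scaling, library totals without TMM, no filter, a filter at a mean FPKM of 5, edgeR's own filter, robust edgeR, DESeq2 1.42.0, the replicate number as a block, and leaving out each sample in turn. For the limma settings, the fold change is on the log2(FPKM + pseudocount) scale. It understates changes of low genes.

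The procedure was tested on simulated data for the same comparison, with counts drawn for the 22964 genes. It recovered 7 of 67 genes changed 1.5-fold, 51 of 67 changed 2-fold and 65 of 66 changed 4-fold. Of its 137 calls 14 were false, a larger share than the adjusted p threshold sets. The simulation changed far fewer genes than the 7289 called in the real comparison. The Benjamini-Hochberg cutoff is stricter when fewer genes change, so these recovery rates do not carry over to the real comparison. The enrichment step recovered the planted term of 200 simulated terms and called no other. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, enrichment and plots. Coordinates are not given because the genome build is not stated.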

Results

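The series asked how gene expression in the intestine of rainbow trout responds to IHNV. RNA was sequenced from 3 intestine samples taken 48 h after injection of the virus and 3 taken 48 h after injection of M199, with total counts between 13530619 and 31142883 per sample. All values below compare these groups with n = 3 each, as mean normalised CPM ± SD, and changes are log2 fold changes of IHNV over M199 ± SE.

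The samples separated by injection. Across genes, the Pearson correlation of log2(FPKM + 1) lay between 0.982 and 0.987 for samples of the same group and between 0.912 and 0.939 for samples of different groups. The first principal component held 76.5% of the variance and parted the groups, and the second held 8.1%. M199 replicate 1 lay nearest to the IHNV samples on the first component, at -36.7 against -47.7 and -50.2 for the other M199 samples.

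The intestine of IHNV-injected fish showed a broad rise of antiviral and chemokine transcripts, together with lower levels of most red blood cell transcripts and of some replication, collagen and epithelial genes. Of 22964 genes tested, 7289 differed between the groups by edgeR's quasi-likelihood test at an adjusted p of 0.05, 3813 higher and 3476 lower after IHNV. At least 2-fold changes among them numbered 2300, 1515 higher and 785 lower, against 1294 and 1145 with library totals in place of TMM and 1246 and 1000 with limma at a pseudocount of 0.1. For all called genes, with library totals in place of TMM the split was 2876 higher and 5188 lower, and with limma on log2(FPKM + 1) it was 2827 higher and 5101 lower. These scalings shift the median log2 fold change of all genes to -0.13 and -0.10. With TMM it was -0.0024. Changes are given relative to the TMM scale. The 3 values of each group did not overlap for 10810 genes, 47.1% of those tested, where chance gives 10%. In the authors' deposited table, 7517 rows passed an adjusted p of 0.05, and 6233 of the 6444 such rows tested here were also called here, none with the opposite direction.

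The largest rises were in chemokines and interferon-induced genes. A copy of cxcl11.1 (gene ID 110536453), a CXC chemokine of the type induced by interferon, had no count in the M199 samples and 38.8 ± 8.8 CPM in the IHNV samples, at least 879.6-fold higher. A second copy (gene ID 100301634) rose from 0.732 ± 0.34 to 106 ± 24 CPM, a log2 fold change of 7.18 ± 0.29 (edgeR adjusted p = 5.3e-06), and copies 118937413 and 100135977 rose by 7.82 ± 0.35 and 6.86 ± 0.40. The antiviral gene rsad2 (viperin, gene ID 110498119) rose from 3.13 ± 2.9 to 223 ± 31 CPM, and its second copy (gene ID 100135876) from 14.0 ± 12 to 668 ± 85 CPM. A polyubiquitin-like gene with the symbol UBB (gene ID 118936268) went from 19.3 ± 16 to 1302 ± 120.1 CPM. M199 replicate 1 was the highest M199 sample for UBB, both rsad2 copies and cxcl11.1 copies 118937413 and 100135977. Without it the log2 fold changes were 8.79 and 8.38 for these cxcl11.1 copies, 7.32 (from 6.17) and 6.54 (from 5.59) for the rsad2 copies and 7.01 (from 6.08) for UBB. Without M199 replicate 3 those cxcl11.1 copies stood at 7.14 and 6.16. The other genes among the 12 largest rises were Ifit1 with a log2 fold change of 6.06 ± 0.39, the cerebellin-like CBLN1 with 6.40 ± 0.40, a receptor-transporting protein 3-like gene (gene ID 110496945) with 6.85 ± 0.27, a gene described as saxitoxin and tetrodotoxin-binding protein 2 (gene ID 110488797) with 6.70 ± 0.46 (7.51 without M199 replicate 3), and a pair of genes without a count in M199 samples. Of that pair, a gene described as cdc42-interacting protein 4 (gene ID 110539048) was at least 82.0-fold higher and an assembled locus described as interferon-inducible Gig2 at least 34.3-fold higher.

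The largest falls were smaller than the largest rises and included cytokine, mucosal and matrix genes. Transcripts described as interleukin-17A (gene ID 110504334) and interleukin-17F (gene ID 110505720), cytokines of mucosal defence, fell by log2 fold changes of -4.27 ± 0.80 and -3.22 ± 0.53 (edgeR adjusted p = 0.0044 and 0.0022), or -5.23 and -4.10 without IHNV replicate 2. The copy il-17a fell from 4.82 ± 2.9 to 0.512 ± 0.48 CPM (edgeR adjusted p = 0.013), a call that ended without IHNV replicate 1 (adjusted p = 0.051), and its log2 fold change of -3.15 went to -4.24 without IHNV replicate 3. Slc34a2, a sodium-dependent phosphate transporter of epithelia, fell from 67.2 ± 17 to 6.80 ± 2.7 CPM, and Bo17, described as a glycosyltransferase that makes branched mucin-type glycans, from 67.4 ± 28 to 6.44 ± 4.0 CPM (log2 fold change of -3.38, and -4.005 without IHNV replicate 3). A claudin-4-like gene with the symbol CLDN6 (gene ID 110525805) fell from 7.27 ± 0.60 to 0.681 ± 0.29 CPM. Other claudin-4-like rows, with the symbol CLDN5, went both ways. Copy 110523410 rose from 4.92 ± 0.78 to 15.9 ± 0.68 CPM, and copy 110536197, named outside the rule, fell from 4.91 ± 0.14 to 1.63 ± 0.42 CPM. The matrix genes Mfap2 and Spon2 fell by -3.39 ± 0.35 and -3.24 ± 0.24, and S100a1 fell by -3.18 ± 0.24. The protease gene hcea, a transmembrane 4 L6 family locus and a type-4 ice-structuring protein-like gene completed the 12 largest falls, at -3.51 ± 0.40, -3.23 ± 0.38 and -3.81 ± 0.76. Without IHNV replicate 1 hcea stood at -4.33. The last of these was no longer called with robust moderation (adjusted p = 0.055 in edgeR and 0.072 in limma).

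**Figure D1:**
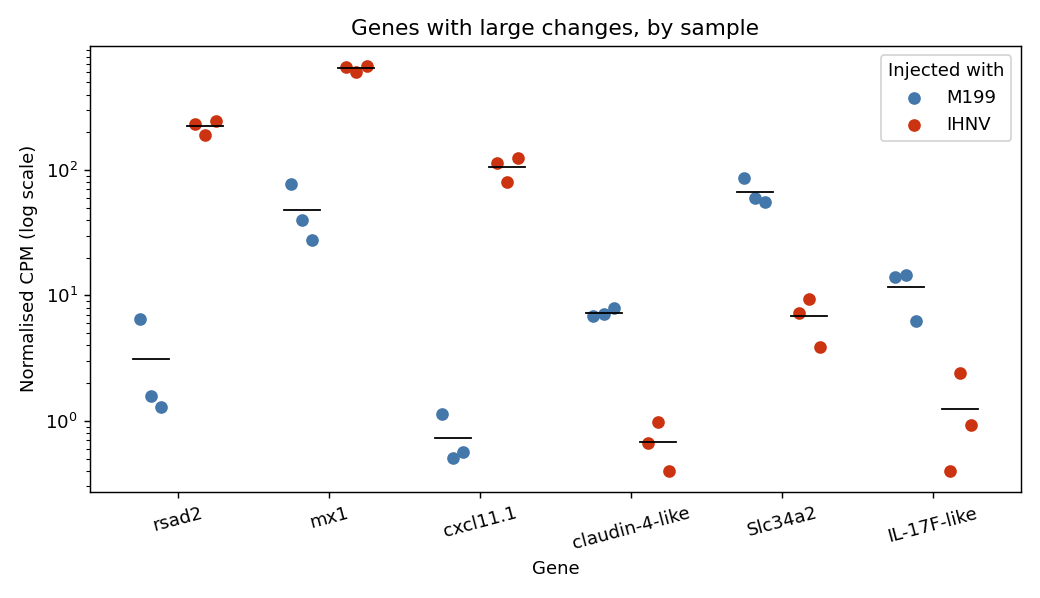
Normalised CPM on a log axis of 6 genes in each sample, with M199 samples in blue, IHNV samples in red and a black line at each group mean. For each gene the 3 IHNV samples lie apart from the 3 M199 samples. Means were 3.13 and 223 CPM for rsad2, and 7.27 and 0.681 CPM for the claudin-4-like gene with the symbol CLDN6.

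Among the 31 lists, interferon-stimulated genes moved the most. Of 193 members tested, 154 rose, 8 fell and 31 did not pass, with a median log2 fold change of 2.08. Adjusted over the list alone, 160 rose and 10 fell. An IFI44L locus, an interferon-induced gene, rose from 63.6 ± 6.1 to 618 ± 44 CPM, the RNA-editing enzyme ADAR from 43.8 ± 2.7 to 209 ± 17 CPM, and the ubiquitin ligase locus rnf213a from 111 ± 8.5 to 620.3 ± 25 CPM. The antiviral GTPase gene mx1 rose from 48.1 ± 26 to 646 ± 38 CPM (edgeR adjusted p = 0.00011), whereas an Mx2-like copy (gene ID 110536470) fell from 198 ± 32 to 109 ± 13 CPM (edgeR adjusted p = 0.0022). The row described as irf7, a transcription factor that drives interferon genes, rose from 53.6 ± 23 to 324 ± 25 CPM. Summed over the list, M199 replicate 1 stood at 7352 CPM, above 5968 and 5349 CPM in M199 replicates 2 and 3, and the IHNV samples stood between 30820 and 34020 CPM. The camera test called the list higher (adjusted p = 1.8e-78), a call lost at an adjusted p = 0.21 with an estimated correlation. By fry it was also called higher (adjusted p = 0.0016).

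In the viral sensing list 69 of 99 members rose, 4 fell and 26 did not pass, with a median of 0.96. Adjusted over the list alone, 72 rose and 6 fell. Cgas, a sensor of cytosolic DNA, rose by 3.81 ± 0.17, sting1, which relays its signal, by 2.63 ± 0.16, Unc93b1, a chaperone of endosomal Toll-like receptors, by 2.63 ± 0.14, and the kinase gene Ikbke by 1.85 ± 0.10. The list also held 42 rows annotated with TRIM25, of which 25 rose and 4 fell. In the MHC class I list 29 of 56 members rose, 2 fell and 25 did not pass, with the same numbers adjusted over the list alone. The peptide transporter gene TAP1 rose from 89.2 ± 4.7 to 267 ± 19 CPM and TAPBP, which loads peptides, from 101 ± 6.8 to 306 ± 11 CPM. The most abundant b2m copy (gene ID 110491889), the light chain of class I, changed by 0.48 ± 0.13 (edgeR adjusted p = 0.026). That call ended without any of M199 replicates 2 and 3 or IHNV replicates 2 and 3 (adjusted p from 0.062 to 0.077). Of 7 copies described as beta-2-microglobulin and tested it was the 1 called. Copy 110491891 had 1003 ± 211 and 1186 ± 141 CPM (edgeR adjusted p = 0.31). With an estimated correlation neither list was called (adjusted p = 0.21 for viral sensing and 0.36 for MHC class I). Fry called both higher (adjusted p = 0.0017 and 0.0033).

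Of 84 inflammatory cytokines and chemokines tested, 31 rose, 19 fell and 34 did not pass, with 32 higher and 20 lower adjusted over the list alone. All 10 CXCL11-type and all 4 CCL19-type chemokine rows rose, among them ccl19a.1 from 14.5 ± 3.4 to 523 ± 56 CPM, a chemokine that attracts lymphocytes and dendritic cells. Il1b (gene ID 110509557) stood at 9.90 ± 1.1 and 9.11 ± 1.1 CPM (edgeR adjusted p = 0.59) and an interleukin-8-like gene at 1.65 ± 0.15 and 2.07 ± 0.36 CPM (edgeR adjusted p = 0.34). No row of tnf or ifng passed the filter on low values, so neither was tested. Over all copies, raw counts of ifng were 10 in M199 and 57 in IHNV samples, and those of tnf 93 and 94. The list included 15 rows described as TNF alpha-induced proteins, which are not cytokines, 6 of them higher and 2 lower. In the list of cytokine and innate signalling feedback 33 of 56 members rose, 3 fell and 20 did not pass, and 35 rose and 6 fell adjusted over the list alone. SOCS1, an inhibitor of cytokine signalling, rose from 4.83 ± 1.4 to 52.5 ± 11 CPM, and TNFAIP2 from 9.95 ± 0.59 to 93.9 ± 21 CPM. With an estimated correlation, the adjusted p = 0.21 for cytokines and 0.35 for feedback. Both lists were called higher by fry (adjusted p = 0.0024 and 0.0033).

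Of 62 heat shock genes 30 rose, 8 fell and 24 did not pass, with 36 higher and 8 lower adjusted over the list alone. All 11 rows described as heat shock protein 70 rose, with log2 fold changes from 1.30 to 4.92. The cognate form hsc71 rose by 2.08 ± 0.10, and hsp90a.1 (gene ID 110529844), a chaperone, rose from 3.67 ± 0.99 to 230.1 ± 42 CPM. In the immediate early list 29 of 76 members rose and 12 fell, with 33 and 14 adjusted over the list alone. A JUN locus rose by 4.16 ± 0.20 and DUSP1, a phosphatase of MAP kinases, from 36.0 ± 3.3 to 111 ± 3.5 CPM. This call ended with a filter at a mean FPKM of 5 (adjusted p = 0.48) and without a filter (adjusted p = 0.096, where the median turned to -0.033 from 0.20). With an estimated correlation the adjusted p = 0.21 for heat shock proteins and 0.62 for immediate early genes. Fry called these lists higher (adjusted p = 0.0017 and 0.014).

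Innate effector genes of the liver and mucosal type changed in both directions. In the complement list 9 of 29 members rose, 2 fell and 18 did not pass, with 9 and 3 adjusted over the list alone. All 3 rows of C3, the central complement protein, rose, as from 3.71 ± 0.64 to 32.6 ± 8.6 CPM (gene ID 110489027). The complement call ended without M199 replicate 1 (adjusted p = 0.062), with a filter at a mean FPKM of 5 (adjusted p = 0.91) and with quantile normalization (adjusted p = 0.082, where the list's median turned to -0.011 from 0.14). The adjusted p = 0.52 with an estimated correlation, while fry called the complement list higher (adjusted p = 0.0098). Of 62 acute phase and antimicrobial genes 14 rose and 18 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.59), with a median of -0.30 and a mean of 0.21. A cathelicidin gene (gene ID 100136187), an antimicrobial peptide, rose from 7.40 ± 4.0 to 141 ± 28 CPM and Saa3, an acute phase protein, from 4.89 ± 3.3 to 83.3 ± 6.6 CPM (log2 fold change of 4.004, and 4.78 without M199 replicate 3), whereas 9 of 15 S100 rows fell and 1 rose. In the goblet cell and mucus list 25 of 76 members rose and 11 fell, with 26 and 11 adjusted over the list alone. Mucin-2-like MUC3B (gene ID 118965994) rose from 59.8 ± 5.1 to 269 ± 12 CPM. Another mucin-2-like row (gene ID 110531777), named outside the rule, fell from 27.8 ± 1.4 to 6.67 ± 0.92 CPM. Of 56 rows with a mucin name, grouped after their values were seen, 20 rose and 7 fell. The list held PARP12 (gene ID 110500034), described as mucin-2 but named as an interferon-induced enzyme, which rose by 1.65 ± 0.09. The goblet call (adjusted p = 0.047) ended without M199 replicate 1, M199 replicate 2 or IHNV replicate 3 (adjusted p = 0.105, 0.073 and 0.052), with quantile normalization (adjusted p = 0.070), with edgeR's own filter (adjusted p = 0.16) and with members taken by symbol alone (adjusted p = 0.98). The adjusted p = 0.36 with an estimated correlation, while fry called the goblet list higher (adjusted p = 0.0024). Without a filter its median turned to -0.19 (adjusted p = 0.76).

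Transcripts of red blood cells were lower. Of 36 members 31 fell, none rose and 5 did not pass, with a median of -0.96, and 32 fell adjusted over the list alone. All 21 hemoglobin rows tested fell, with a median log2 fold change of -1.08; hba1 (gene ID 110538448) went from 94.1 ± 9.1 to 40.3 ± 3.7 CPM. The sum over the list was 1302 ± 168 CPM in M199 and 705 ± 28 CPM in IHNV samples. The camera call (adjusted p = 4.4e-14) was lost at an adjusted p = 0.33 with an estimated correlation. By fry the list was called lower (adjusted p = 0.0041).

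In the cell cycle list 22 of 60 members fell, 1 rose and 37 did not pass, with 28 lower and 1 higher adjusted over the list alone. Of the 9 rows of the MCM replication licensing factors 8 fell, rrm1, a subunit of ribonucleotide reductase, fell by -1.04 ± 0.10, and ccnd1, a cyclin of G1 phase, was the member that rose, from 50.2 ± 3.2 to 87.9 ± 4.6 CPM. Of 39 cholesterol genes 17 fell and 1 rose, with 19 and 1 adjusted over the list alone. The reductase gene dhcr7, which acts at the end of the pathway, went from 41.7 ± 0.77 to 22.6 ± 0.65 CPM, and insig1, which restrains the pathway, rose from 40.9 ± 8.3 to 159 ± 6.0 CPM. Of 69 genes of fatty acid oxidation 28 fell and 7 rose, with 30 and 7 adjusted over the list alone. ACOX3, a peroxisomal oxidase, went from 147 ± 6.1 to 80.6 ± 1.9 CPM, and a pair of rows of Pdk2, a kinase that inhibits pyruvate dehydrogenase, rose by 2.41 ± 0.26 and 1.57 ± 0.18. The last list was not called without M199 replicate 1 (adjusted p = 0.098) or without a filter (adjusted p = 0.054). With an estimated correlation the adjusted p = 0.73 for the cell cycle, 0.52 for cholesterol and 0.21 for fatty acid oxidation. Fry gave an adjusted p = 0.086 for the cell cycle. It called cholesterol and fatty acid oxidation lower (adjusted p = 0.022 and 0.0024).

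In the extracellular matrix list 36 of 75 members fell, 13 rose and 26 did not pass, with 38 and 15 adjusted over the list alone. Of 24 collagen rows 16 fell and 1 rose. COL6A2 went from 130.1 ± 26 to 48.2 ± 1.3 CPM, and MMP2, a collagenase, from 99.1 ± 21 to 42.1 ± 1.3 CPM, while Mmp14 rose by 1.71 ± 0.20. M199 replicate 3 was the highest sample in the summed CPM of the matrix list (10660 against 7647 and 8859 in the other M199 samples), of smooth muscle (9498 against 7380 and 7913), of the cell cycle (1238 against 854 and 994) and of red blood cells (1494 against 1232 and 1180). Without it the medians of these lists went from -0.36, -0.35, -0.62 and -0.96 to -0.24, -0.23, -0.39 and -0.82, each still called lower by camera (adjusted p of at most 0.030). In the smooth muscle list 20 of 52 members fell and 2 rose, with 23 and 2 adjusted over the list alone. Synpo2 (gene ID 110531746), an actin-binding protein, fell by -1.54 ± 0.14, and a myosin-11-like gene (gene ID 110524132) rose from 33.4 ± 5.0 to 190.2 ± 18 CPM. Neither call held with fry (adjusted p = 0.17 for the matrix and 0.054 for smooth muscle) or with an estimated correlation (adjusted p = 0.77 and 0.73). The matrix call also ended without IHNV replicate 2 (adjusted p = 0.051), without a filter (adjusted p = 0.095) and with limma at a pseudocount of 0.1 (adjusted p = 0.061).

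**Figure D2:**
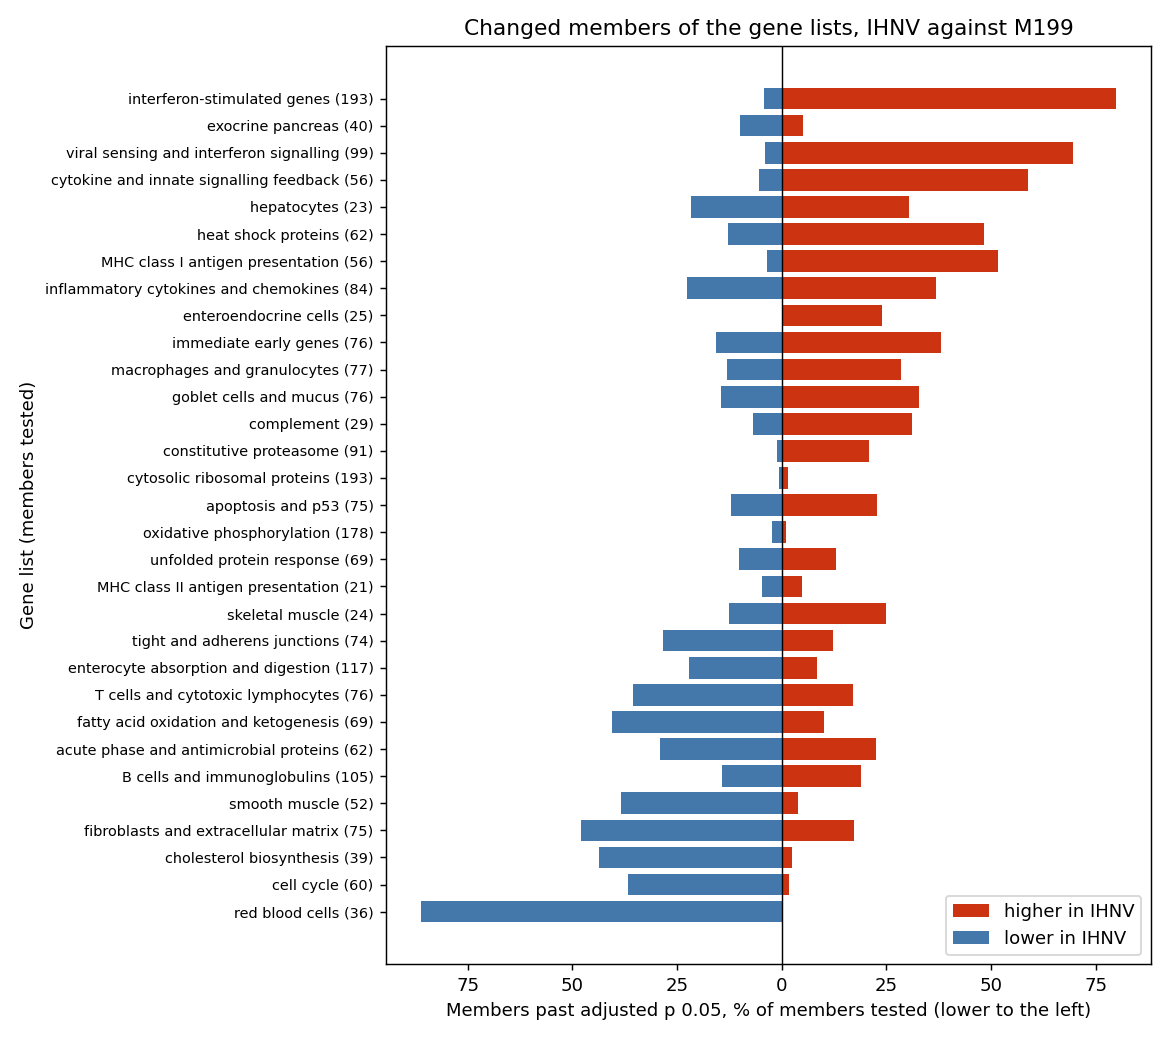
Share of the tested members of each gene list that rose (red, to the right) or fell (blue, to the left) at an edgeR adjusted p of 0.05, in percent, with the number of members tested in brackets and the lists in order of their median log2 fold change. Interferon-stimulated genes are at the top with 154 of 193 members higher, and red blood cells at the bottom with 31 of 36 lower.

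The other lists were not called by camera. Of 76 T cell and cytotoxic lymphocyte genes 13 rose and 27 fell, with 15 and 28 adjusted over the list alone (adjusted p = 0.064, and 0.030 without M199 replicate 2 and 0.043 without IHNV replicate 3). BCL11B, a T cell transcription factor, fell by -0.86 ± 0.12. The coreceptor gene cd8a changed by -0.57 ± 0.18 (edgeR adjusted p = 0.038, lost at 0.058 to 0.11 when any sample but M199 replicate 3 was left out). Of the perforin-1-like rows, which encode a pore-forming protein of killer cells, an assembled locus fell by -1.54 ± 0.15 and Prf1 rose by 1.58 ± 0.22. In the B cell list 20 members rose, 15 fell and 70 did not pass, with 20 and 16 adjusted over the list alone. Its 14 CD22-like or sialoadhesin-like rows, which need not all be B cell genes, included 10 that rose. Of 48 immunoglobulin chain rows 8 fell and 1 rose. Of 77 macrophage and granulocyte genes 22 rose and 10 fell, with 25 and 11 adjusted over the list alone, among the former MMP9, a protease of granulocytes, from 11.3 ± 4.6 to 121 ± 36 CPM; this list was called without IHNV replicate 2 (adjusted p = 0.044) and with limma on log2(FPKM + 1) (adjusted p = 0.035). MHC class II genes had 1 of 21 members higher and 1 lower, also when adjusted over the list alone.

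Among epithelial lists, 26 of 117 enterocyte genes fell and 10 rose, also when adjusted over the list alone (camera adjusted p = 0.10, and 0.039, 0.038 and 0.026 without M199 replicate 2, M199 replicate 3 and IHNV replicate 1, and 0.049 with quantile normalization). The anion exchanger gene Slc26a6 fell by -1.53 ± 0.13 and the amino acid transporter gene Slc6a19 rose by 0.71 ± 0.10. The fatty acid binding gene fabp2 (gene ID 110534299) had 1639.7 ± 303 CPM in M199 and 1100.4 ± 196 CPM in IHNV samples (edgeR adjusted p = 0.040), a call that ended when any sample but M199 replicate 2 was left out (adjusted p from 0.063 to 0.11). Of 3 fabp2 copies tested it was the 1 called, and FABP2 copy 110500773 had 1175 ± 204 and 1014 ± 200.4 CPM (edgeR adjusted p = 0.40). Of 74 junction genes 21 fell and 9 rose, with 23 and 9 adjusted over the list alone, and fry called the list lower (adjusted p = 0.021). Among 25 claudins, which seal tight junctions, 10 fell and 5 rose, the latter including CLDN1 with a log2 fold change of 3.90 ± 0.24. Of 25 enteroendocrine genes 6 rose and none fell, also when adjusted over the list alone, among them scg3, a secretogranin of hormone granules, by 0.46 ± 0.09; the list was called by limma on log2(FPKM + 1) (adjusted p = 0.024).

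Few members passed in the lists of oxidative phosphorylation (2 higher and 4 lower of 178) and cytosolic ribosomal proteins (3 higher and 1 lower of 193); adjusted over the list alone none of the former and 1 of the latter passed, higher. Oxidative phosphorylation was called lower with limma after quantile normalization (adjusted p = 0.0034), with a pseudocount of 5 (0.024) and with array weights (0.046). The proteasome list had 19 higher and 1 lower of 91, with 18 and 1 adjusted over the list alone (camera adjusted p = 0.075), with PSMA6 (gene ID 110503695) from 32.4 ± 2.9 to 61.3 ± 1.2 CPM. It was called higher without IHNV replicate 1 (adjusted p = 0.041), without a filter (0.0056), with edgeR's own filter (0.022), with fry (0.022) and with limma except after quantile normalization (0.024 to 0.045). The apoptosis list had 17 higher and 9 lower of 75 (17 and 11 adjusted over the list alone; fry adjusted p = 0.036, higher), with CASP6, a caspase, from 138 ± 14 to 278 ± 34 CPM, and the unfolded protein response list 9 higher and 7 lower of 69 (9 and 4 adjusted over the list alone; median -0.03, mean 0.09), with DNAJC3, a co-chaperone of the endoplasmic reticulum, from 0.559 ± 0.42 to 11.7 ± 0.63 CPM (log2 fold change of 4.63, with 5.25 without M199 replicate 2 and 4.03 without M199 replicate 3). Of 23 hepatocyte genes 7 rose and 5 fell, with 7 and 6 adjusted over the list alone, among the former FGG, a fibrinogen chain, from 5.82 ± 1.5 to 44.3 ± 9.8 CPM. Serum albumin (alb1) had 3.52 ± 0.99 and 12.4 ± 17 CPM (edgeR adjusted p = 0.18). Its IHNV level came from IHNV replicate 2, and without that sample the log2 fold change went from 1.79 to -0.58 (edgeR adjusted p = 0.19). The skeletal muscle list, with 6 higher and 3 lower of 24 (also adjusted over the list alone), held 17 titin-like rows and had a median of -0.07 but a mean of 0.19 (fry adjusted p = 0.041, higher). Exocrine pancreas genes had 2 higher and 4 lower of 40 (1 and 4 adjusted over the list alone), the latter including Prss35 rows, which are not pancreatic enzymes. The pancreas sum was 3285 and 4027 CPM in IHNV replicates 1 and 3 but 380.1 CPM in IHNV replicate 2, against 830.7 to 1817 CPM in M199 samples, and without IHNV replicate 2 the list was called higher (adjusted p = 8.1e-05).

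**Figure D3:**
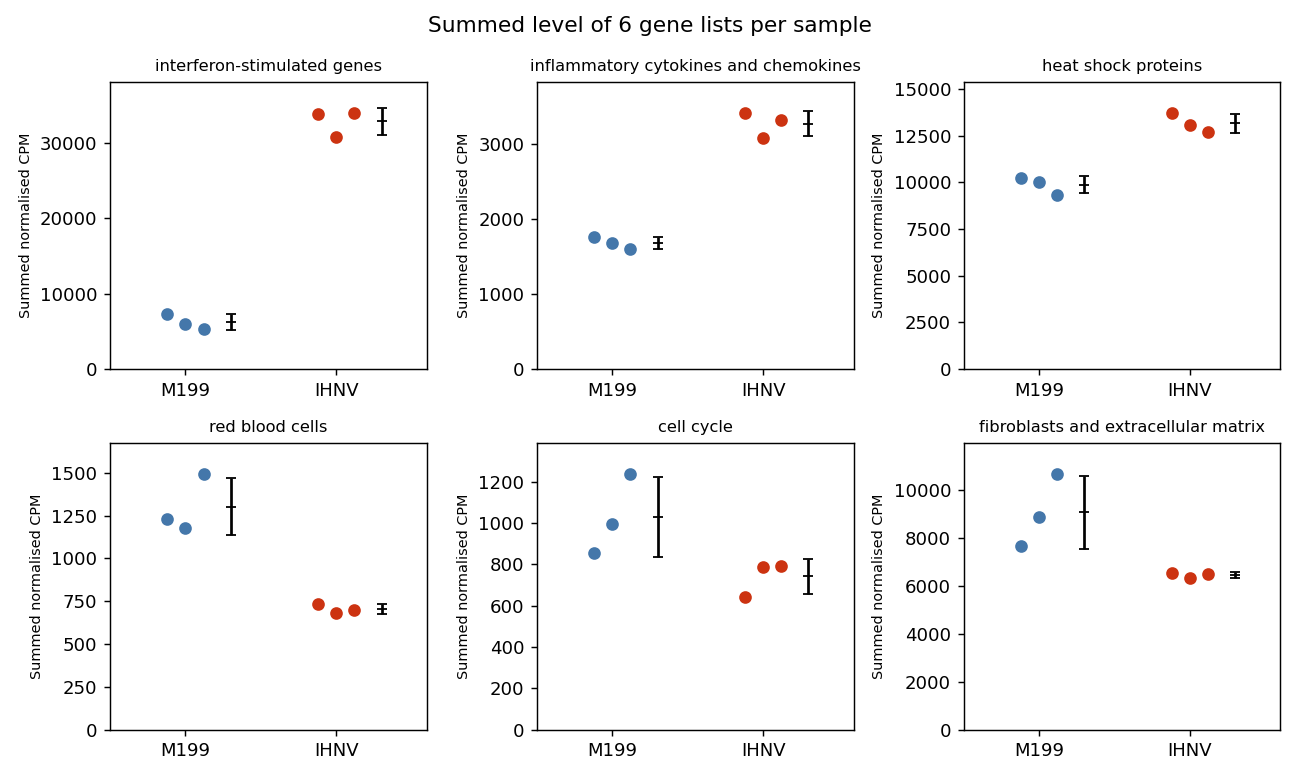
Summed normalised CPM of 6 gene lists in each sample (M199 samples in blue, IHNV samples in red), with the group mean and SD as a bar beside the points; each axis starts at 0. Interferon-stimulated genes summed to between 5349 and 7352 CPM in M199 and between 30820 and 34020 CPM in IHNV samples, and red blood cell genes to 1302 and 705 CPM.

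Terms of the deposited annotation gave a second grouping of the changed genes. Among KEGG pathways, 77 of 308 were enriched among genes higher after IHNV and 35 among genes lower. The higher set was led by NOD-like receptor signaling with 109 of 274 tested genes higher (one-sided Fisher's exact test, adjusted p = 5.55e-19), RIG-I-like receptor signaling with 58 of 101 (the same adjusted p) and cytokine-cytokine receptor interaction with 109 of 282. The lower set was led by amino sugar and nucleotide sugar metabolism with 34 of 76 lower (one-sided Fisher's exact test, adjusted p = 1.5e-06), fatty acid degradation with 30 of 64 and DNA replication with 23 of 47. Of 1691 GO processes 59 were enriched among genes higher and 32 among genes lower, led by cytokine-mediated signaling with 70 of 150 higher and gas transport, which holds the globins, with 24 of 29 lower. Copies of a gene carry the same terms, so these tests count duplicated genes several times.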

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

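Library totals without TMM, robust edgeR, edgeR's own filter, DESeq2 and the correlation on log2 CPM were chosen after seeing the data. The limma fit on log2(FPKM + 1) was written beforehand as the main test, with edgeR to replace it for counts. Keeping it beside edgeR as an alternative was decided after seeing the data. Of 159 named genes, 147 stayed on their side of the threshold under every alternative that gave them a result. Some alternatives, such as the filter at a mean FPKM of 5, did not test every named gene. No called gene changed direction, while the uncalled genes IGHV1-46, IGHV3-43 and alb1 did under some alternatives. Of 3450 gene results, 61 were no longer past the threshold and 5 were newly past it. Of 744 list results 35 lost and 41 gained the call, and no called list was called in the opposite direction. Of the 7289 genes called, 6270 were also called in the same direction by limma on log2(FPKM + 1), 7239 with median-of-ratios scaling and 6748 by DESeq2.

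A filter at a mean FPKM of 5 tested 10827 genes and called 4110, 2141 higher and 1969 lower, with 1115 at least 2-fold (859 higher, 256 lower). An adjusted p of 0.01 left 4225 genes. The count of genes changed at least 2-fold was 1376 (959 higher, 417 lower) with limma on log2(FPKM + 1) and without trend, 687 (557 higher, 130 lower) with a pseudocount of 5, which shrinks the changes of low genes, 1373 (991 and 382) with quantile normalization, 1346 (947 and 399) with robust limma and 1382 (971 and 411) with array weights. It was 3471 without a filter, 1503 of them lower, and edgeR's own filter gave 1397 lower; both tested more genes. The cause of the other differences was not tested. Camera with an estimated correlation called 0 lists, with 5 at an unadjusted p under 0.05, against 15 with the preset correlation and 16 with fry. The gap between the lowest correlation within and the highest between groups was 0.042 by Pearson on log2(FPKM + 1), 0.055 by Spearman and 0.053 on log2 CPM.

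Leaving out 1 sample in turn gave 5421 to 6442 genes (3008 to 3445 higher and 2413 to 2997 lower), 2169 to 2487 at least 2-fold (1441 to 1603 higher and 665 to 884 lower) and 12 to 17 lists. The replicate number as a block gave 7099 genes (3683 higher and 3416 lower), 2318 at least 2-fold and 16 lists. Deviations of samples of the same number correlated by 0.036, 0.13 and -0.0072, against -0.14 to 0.098 for samples of different numbers. No clear pairing by number was seen, but 3 samples per group cannot exclude it.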

Other observations

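The gene families here, some of whose rows are also members of the lists above, were picked after their values were seen, so their tests describe these samples and are not independent evidence. Of 17 HERC ubiquitin ligase rows, a family with interferon-induced members, 11 rose and 2 fell, with a median log2 fold change of 4.45 (one-sided Fisher's exact test among all genes tested, adjusted p = 8.5e-05). HERC6 copies 118941453 and 110519118 rose by 5.98 ± 0.40 (6.67 without M199 replicate 1) and 5.52 ± 0.34. Of 229 TRIM protein rows 120 rose and 20 fell, and of 40 poly(ADP-ribose) polymerase rows 27 rose and 3 fell, led by a PARP12 copy (gene ID 110497974) at 5.06 ± 0.21. Of 49 GTPases of the GIMAP family, which are expressed in lymphocytes, 25 rose and 1 fell. The median of each of these families stayed above 0 under the 6 scalings compared.

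Of 12 membrane-spanning 4-domains rows 6 fell and none rose, led by gene ID 110506734 at -2.66 ± 0.21. Chitin synthase chs-2 (gene ID 110499397) fell by -2.39 ± 0.20, and a pair of polyketide synthase pks2 rows by -2.37 ± 0.42 and -1.99 ± 0.34. Of 41 genes with endothelial descriptions or symbols, a mixed group, 13 fell and 6 rose. The apelin receptor aplnrb and plvapb, both known from blood vessels, fell by -2.68 ± 0.20 and -2.37 ± 0.26, while LYVE1, a receptor of lymphatic vessels, rose by 2.71 ± 0.29.

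Other splits of the 6 samples into 3 and 3 were tested as planned, and the remaining tests below were chosen after the results were seen. Only 10 such splits exist, too few for a share under 0.05. Each of the others puts samples of both injections on each side, so the injection difference adds to the spread within groups. A low number of gene calls in those splits was thus built into the design. The real split gave 7289 genes by edgeR and the highest of the others 0 (with 231 to 694 genes at an unadjusted p under 0.05), so 1 of the 10, the real one, gave as many; for genes changed at least 2-fold the real value was 2300 and the highest other 0, again 1 of 10. For lists called by camera with the preset correlation, 4 of the 10 splits gave as many, the real one included, with 15 lists in the real split and 17 in the highest other. The other splits mix the groups unevenly, so part of the difference between IHNV and M199 stays in them. Whether that, or genes of a list varying together, gave their list calls was not tested. The member counts by edgeR carry more weight here than the number of lists called.

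Red blood cell transcripts were about 2-fold lower after IHNV. The list's median lay between -1.09 and -0.954 over the 6 scalings compared. Its distance to the median of all genes (-0.861 at the least) says nothing on scaling, since a library factor moves both alike. Less blood in the IHNV tissue would lower erythrocyte transcripts by 1 shared factor, and the 29 such transcripts fell by a median of -0.97 with an SD of 0.366, 2.52 times their median standard error of 0.146. Standard errors differ between these transcripts, so a few poorly measured ones can widen the SD past that of a typical transcript. Copies that share reads, or that other cells of the gut express, may widen it too. The ratio therefore cannot decide whether 1 shared factor is the whole cause. Fewer red cells in the fish would also act by 1 shared factor, so it and less blood stay open as the whole or part of the cause. Less RNA per red cell, which can differ between genes, stays open and was not tested.

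M199 replicate 1 stood higher in interferon-stimulated genes than the other M199 samples. Of the 154 members that rose, 108 were highest in it among the M199 samples, against 33.1% of all genes tested, and the median ratio to the other M199 samples was 1.30. Its total count ranked 2 of 3, so deeper sequencing of that library does not account for this. Carry-over of RNA or reads from IHNV libraries could not be told apart from a response in that sample. Of 75 chemokine, heat shock and acute phase genes 2 lay below the count that carry-over predicts, where the test asked for more than 5. These were cxcl11.1 copy 110536453 (0 counts) and an hsp70 copy (gene ID 118938279, 0 counts where 19.5 were predicted). That hsp70 copy would have had 96.5 counts at the level of the other M199 samples, so its 0 says little on carry-over. Another cxcl11.1 copy (gene ID 100301634) had 23 counts, between 10.9 at the level of the other M199 samples and 41.1 predicted. At the level of the other M199 samples only 2 of the 75 would have fallen below, 1 of them among those that did. The bound of more than 5 was thus out of reach even without carry-over, and this test cannot decide. The 1 gene near 0 in the other M199 samples with enough predicted counts was cxcl11.1 copy 110536453. It had 0 counts where 15 were predicted, which goes against carry-over but is a single gene. The limit of the first test was noticed after it had been run, and the second test was added then. No biological explanation was tested.

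All 5 interleukin-17 rows tested fell, with a median of -3.15, although the calls of the copies il-17a, il17a/f3 and il17a/f1 ended when some single samples were left out (adjusted p up to 0.051, 0.073 and 0.079). Without IHNV replicate 3, il17a/f1 went from -2.84 to -4.56. Fewer T cells in the IHNV samples would lower T cell transcripts alike, but the median of 30 T cell receptor, CD3 and T cell kinase rows was -0.295, which lies 2.86 above the interleukin-17 median, beyond the larger SD of 1.03. Loss of T cells as a whole is therefore an unlikely sole cause, although the interleukin-17 rows were picked after their falls were seen. Of the 30 T cell rows 11 fell and 4 rose, so fewer T cells stay open as part of the cause. Loss of a small subset that makes interleukin-17, or lower transcription in the cells that remain, may explain the fall and was not tested.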
